A study of Petromyzon marinus with 12 samples.

How the data were processed

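Bulk RNA sequencing had been done on the endostyle of wild-type sea lamprey (Petromyzon marinus) at 4 developmental stages that the labels call T27, T28, T29 and T30, with 3 libraries per stage. The labels do not spell out the staging scheme. Per the labels' protocols, total RNA was extracted with the RNAqueous kit and libraries were built by Illumina standard methods. The groups were taken from the stage in each sample's label. The labels number the replicates 1 to 3 in each stage but do not say that they came from separate animals or pools, so the p-values measure the spread between these samples, which may be technical.

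The authors deposited raw read counts per gene. Per the file headers, the counts were made with featureCounts 1.6.3 on a gene annotation of the kPetMar1 assembly, from files named as the first read of a pair, grouped by gene, with no strand, paired-end or multiple-mapping option in the recorded command. Per the submitters' processing notes, Bowtie2 and DESeq2 were also used. The Bowtie2 version and settings and any read trimming are not given in the sources used here. Bowtie2 does not split a read across an intron, so reads over exon junctions add less to the count of a gene with many short exons, in every library alike. Reads of a gene and of a gene on the opposite strand at the same place cannot be told apart without strand, and how reads shared by near-identical copies were counted is not stated, so values of multigene families such as ribosomal proteins and collagens are less certain than those of single-copy genes. Per the file headers, the gene positions and the exon length in bp also came from that annotation. These positions are printed as the authors' file gives them.

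In a separate table deposited by the authors each value is a score, a z-score by the file's name, which they had standardised within a gene. It holds 1671 genes and 6 columns, for Ciona (a tunicate), the 4 lamprey stages and zebrafish. Tested on the file, each gene's scores across the 6 columns have a mean within 0.003 of 0 and an SD between 0.996 and 1.00, so each score measures a gene against its own mean over the columns. The unit that was standardised, the tissue of the other species and the way genes were matched between species are not given in the sources used here. Each column holds 1 value per gene with no replicate, so the table was only described and no test was run on it.

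The count table has 21967 gene rows, of which 2171 had no count in any library and 2061 are tRNA genes. The rows carry a symbol for 5919 genes, and 13987 rows carry a locus number. Locus numbers were matched by gene ID to the RefSeq gene table of assembly UKy_Petmar_22M1.pri1.0, which is another build, for names alone. That gave a name to 688 locus rows. A further 11183 locus rows stand in that table without a name and 2116 do not stand in it. With 6607 named rows, many members of the gene lists below could not be found, and a member that was not matched is not shown to be absent. The library totals ran from 28371140 to 36032488 counts, and precision is lower for genes at low CPM, which rest on few counts.

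Genes were kept with edgeR's filterByExpr by stage (minimum count 10), which left 16526. Library sizes were scaled by TMM and a quasi-likelihood model was fitted over all 12 libraries with edgeR 4.0.16 in R 4.3.3, leaving 8 residual degrees of freedom. The common dispersion was 0.0154, a biological coefficient of variation of 12.4%. Any change between stages was tested over 3 coefficients, and contrasts were tested for each consecutive step and for T30 against T27. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no fold limit. The word "rose" or "fell" is used below of genes past that threshold. Means and SDs are of TMM-scaled CPM over 3 libraries, and fold changes are from the fit. Their standard errors (SE) were derived as the absolute log2 change divided by the square root of the F of its test. A contrast of the T29 to T30 step with the T27 to T28 step, which share no library, tested whether the steps differed.

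Fixed before the data were examined were 23 gene lists, for thyroid hormone production, thyroid and pharyngeal endoderm regulators, motile cilia, mucus and secretory pathway, cell cycle, mitochondrial respiration, cytosolic ribosomal proteins, developmental signalling, basement membrane, neural crest, stress and immediate early genes, and markers of other tissue (pigment cells, glia, neurons, muscle, cartilage, connective tissue, endothelium, erythroid cells, leukocytes, liver, gill and ionocytes, epithelium). Lists with at least 5 measured members, 21 of them, were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and the p-values were adjusted over the lists within each contrast. The glia and leukocyte lists had 1 measured member each and were not tested. Camera's p with a correlation estimated from these libraries is given beside each call.

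The named genes also followed a rule fixed before the data were examined. The rule selects the called members of both thyroid lists. It also selects the 10 genes that rose most and the 10 that fell most between T27 and T30, and the 4 each way for each step, among called genes with a symbol, a mean log2 CPM of at least 1 and stages whose replicate values do not overlap. In addition come the 4 members with the smallest p, in the list's direction, of each called list, and called neural crest members between T27 and T30. A few genes that the rule selects are not reported here. Also fixed at that time were the alternatives, which were size factors, upper quartile scaling, 2 other filters, DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each library, a threshold of 0.01, a log2 fold of at least 1, a fit of only the stages compared and, for the lists, an estimated correlation and fry. Thinning all libraries to the smallest total and leaving out the 100 most abundant genes were added after seeing the data.

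The fit was tested on simulated counts for T28 against T27 with known changes in 200 of 15863 genes tested. A further list of genes had a smaller shift and entered neither tally below. The fit recovered 60% of 1.5-fold, 86% of 2-fold, 86% of 0.5-fold and 100% of 4-fold changes, with 9 false calls among unchanged genes. Far fewer genes were changed there than were called in the data (26% for T28 against T27 and 60.3% for T30 against T29). The simulation thus does not show how scaling or error rates hold where most genes change. No 2 libraries of a stage held the same values. The chi-square per degree of freedom between replicates ran from 11.0 to 67.8, above sampling noise in each pair, so no library was counted as a duplicate. No genome sequence was used, so GC content was not checked. Figures were drawn with matplotlib 3.10.9 in Python.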

Results

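The endostyle is a glandular groove in the floor of the pharynx of tunicates, lancelets and larval lampreys, and in lampreys it is the tissue from which the thyroid forms at metamorphosis. Endostyle RNA of the sea lamprey was profiled at stages T27, T28, T29 and T30, with 3 libraries per stage. The libraries held 31038776 to 32511089 counts at T27, 32488742 to 34211757 at T28, 33681162 to 36032488 at T29 and 28371140 to 35423591 at T30. The 13 protein-coding genes of the mitochondrial genome took between 1.56% and 2.45% of the counts of a library, and the 100 most abundant genes between 21.1% and 24.7%.

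Stage was the main difference between the libraries. Of 16526 genes tested, 12697 (76.8%) changed between stages in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The first principal component held 68.5% of the variance and placed the T30 libraries between 100.2 and 108.7, against 1.9 or lower for all other libraries. T27 replicate 1 lay at −58.1 on that component, nearer to the T28 libraries than T27 replicates 2 and 3 at −77.5 and −80.2.

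**Figure D1:**
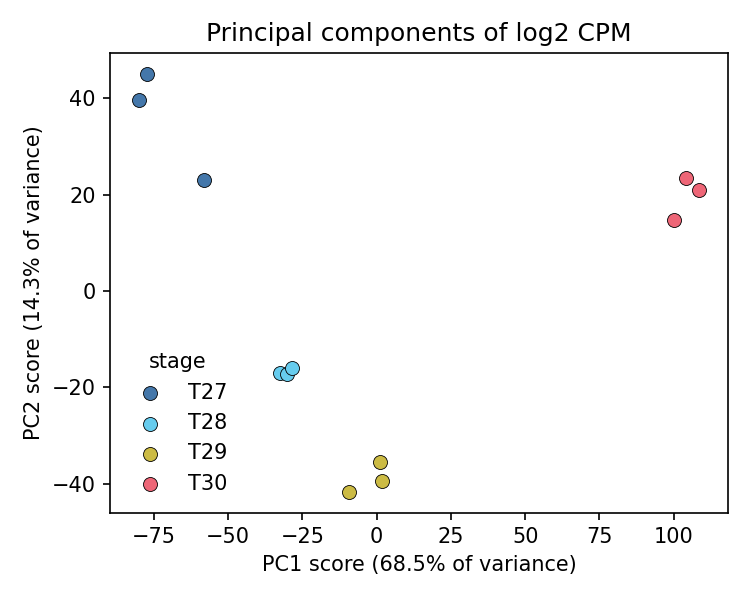
Scores of the 12 libraries on the first and second principal components of log2 CPM (68.5% and 14.3% of the variance), coloured by stage; each point is a library. The T30 libraries stand apart on the first component, and the T29 libraries have the lowest scores on the second, at −41.7 to −35.6.

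The comparison of T30 with T27 asked what changed in the endostyle over the whole span sampled. Several genes of thyroid hormone synthesis rose. SLC5A5, the sodium iodide symporter, went from 5.93 ± 0.902 CPM (SD, n = 3) at T27 to 105.6 ± 12.2 CPM (SD, n = 3) at T30, a 17.8-fold rise (log2 4.15, SE 0.13). IYD, which recovers iodide from iodotyrosines, rose 2.30-fold (log2 1.20, SE 0.10), from 40.6 ± 0.376 to 93.3 ± 10.8 CPM. LRP2, the endocytic receptor megalin, rose 8.86-fold (log2 3.15, SE 0.17).

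Of 11 measured members of the thyroid hormone production list, from 28 fixed, 7 rose and 1 fell, with the same counts adjusted over the list alone. Besides the genes above, the chloride channel ANO1 rose 2.25-fold (SE 0.20 on the log2 scale), the monocarboxylate transporter SLC5A8 rose 1.55-fold (SE 0.19), and the deiodinase DIO2 rose from 0.103 to 2.19 CPM (T27 mean 0.0334 CPM, on 2 counts, without T27 replicate 1). The lysosomal protease CTSB fell from 96.9 ± 9.11 to 20.7 ± 3.0 CPM (SD, n = 3). The list as a whole was not called by camera (median log2 change 1.17, adjusted p = 0.0532, and adjusted p = 0.341 with an estimated correlation), while fry, which does not compare a list with other genes, gave adjusted p = 2.93e-07. SLC5A5 lies on the minus strand of sequence NC_046108.1 of kPetMar1, from 2274675 to 2295804, and IYD on the plus strand of NC_046121.1, from 1797035 to 1808214. Each value is a sum over the gene's annotated exons.

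Transcription factors of the thyroid and pharyngeal endoderm moved both ways, and 5 of 7 measured members rose and 2 fell (also 5 and 2 adjusted over the list alone; camera adjusted p = 0.660). PAX2, of the same family as the thyroid regulator PAX8, rose 1.63-fold to 124.3 ± 8.01 CPM. HHEX, a homeobox gene needed for thyroid formation in other vertebrates, rose 1.29-fold, SOX2 1.55-fold, PAX1 1.48-fold and FOXA2 1.14-fold. The LIM homeobox gene ISL1 fell from 81.4 ± 3.56 to 30.3 ± 2.83 CPM (SD, n = 3), and the pharyngeal pouch gene PAX9 from 20.2 ± 2.22 to 10.1 ± 1.87 CPM. The FOXA2 rise rested on small changes: without T27 replicate 2 its log2 change was 0.15, with an edgeR adjusted p of 0.128, and it was also lost without T27 replicate 3 (adjusted p 0.0689), without T30 replicate 3 (0.0934) and in the fit of only both stages (0.0592).

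**Figure D2:**
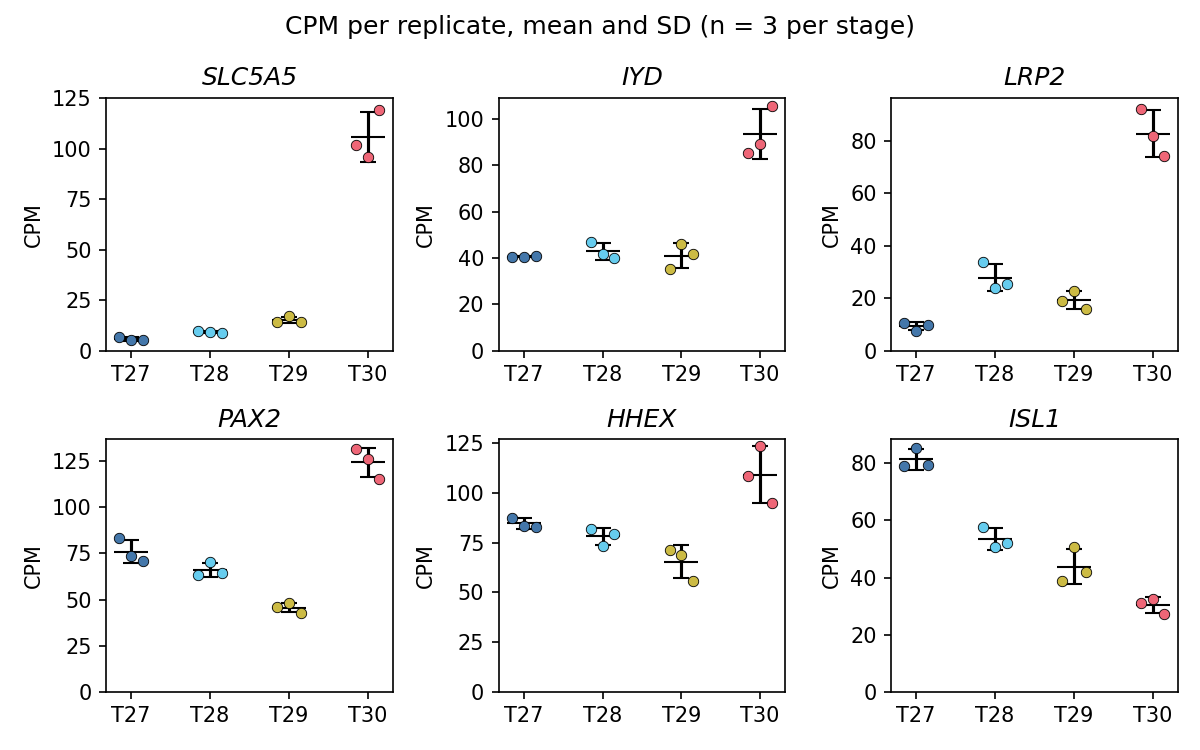
CPM (linear axes from 0) of 6 genes in each library at T27, T28, T29 and T30; points are replicates, the bar is the mean and the whiskers are 1 SD (n = 3). SLC5A5, IYD and LRP2 reached their highest means at T30 (105.6, 93.3 and 82.7 CPM), and PAX2 fell to 45.7 CPM at T29 before it stood at 124.3 CPM at T30.

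Outside the thyroid lists, the cystine transporter SLC7A11 had the highest fold of the named genes, from 0.742 ± 0.214 to 259.5 ± 57.0 CPM (SD, n = 3), 351-fold (log2 8.45, SE 0.30). Another amino acid transporter gene, SLC7A9, rose 39.0-fold. The parathyroid hormone receptor gene PTH1R rose from 0.259 to 27.4 CPM and PEBP4 from 0.618 to 49.0 CPM. AMPD1, the AMP deaminase of muscle, rose 101-fold, CCDC154 53.6-fold, TMEM182 42.9-fold and the thymidine phosphorylase gene TYMP 40.8-fold, and C1QTNF3 went from 0.314 to 10.96 CPM. Without T27 replicate 1 the fold was 74.8 for TMEM182 and 183.8 for PTH1R (103.2 with it), and the C1QTNF3 mean at T27 was 0.0334 CPM, on 2 counts, so the size of its change (log2 5.07, and 4.48 without T27 replicate 2 and 6.67 with voom) is uncertain. Among genes that fell, the receptor gene GPR157 went from 12.7 ± 1.33 to 0.281 ± 0.148 CPM (log2 −5.46, SE 0.26), and ACOD1, which makes itaconate, from 15.3 to 0.515 CPM. The apolipoprotein gene APOC3 went from 66 to 2.80 CPM, CTHRC1 from 32.4 to 1.6 CPM and ALOX5, a lipoxygenase of leukotriene synthesis, from 14.1 to 1.16 CPM. TH, the tyrosine hydroxylase of catecholamine synthesis, had a log2 change of −3.51 (SE 0.29) and MAB21L1 of −3.40 (SE 0.23).

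Cell cycle genes fell together. All 42 measured members, from 63 fixed, fell, also 42 adjusted over the list alone (median log2 change −2.49). The spindle motor KIF11 went from 103.4 ± 4.45 to 11.2 ± 0.784 CPM (SD, n = 3), the mitotic kinase PLK1 from 204.9 ± 9.46 to 18.6 ± 1.72 CPM, the replication licensing factor CDC6 from 26.4 to 2.42 CPM, and SMC4, CENPE and ANLN had log2 changes of −2.48, −2.67 and −2.83. The camera call (adjusted p = 1.56e-21) was lost with an estimated correlation, at adjusted p = 0.112 with an estimated correlation.

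Motile cilia genes rose, 57 of 59 measured members, while 1 fell (57 and 1 adjusted over the list alone; median log2 change 1.09). The axonemal dynein heavy chains DNAH5 and DNAH6 rose 7.99-fold (SE 0.15 on the log2 scale) and 5.49-fold (SE 0.13), and the axoneme genes CFAP65 and CFAP47 rose 3.24-fold and 5.21-fold. The camera call had adjusted p = 9.71e-14, and adjusted p = 0.341 with an estimated correlation.

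Markers of other tissue moved in different directions. All 12 measured muscle genes rose, 12 adjusted over the list alone, with a median log2 change of 2.29. NEB, TCAP, ACTN2 and LDB3, which encode proteins of the sarcomere, rose 17-fold, 12.5-fold, 10.1-fold and 4.61-fold (camera adjusted p = 0.00113, and adjusted p = 0.408 with an estimated correlation). NEB went from 5.13 ± 2.81 to 87.5 ± 36.3 CPM and ACTN2 from 42.3 ± 8.45 to 426.7 ± 131.1 CPM (SD, n = 3). Within T30 both were lowest in replicate 2, at 46.1 and 312.5 CPM, as was TTN at 86.4 CPM against 204.4 and 243.0 CPM, and within T27 NEB was highest in replicate 1, at 8.14 CPM. Of 8 measured pigment cell genes 6 rose, 7 adjusted over the list alone, and none fell. DCT, of melanin synthesis, went from 0.225 to 5.12 CPM and PMEL, of the melanosome, from 0.975 to 3.89 CPM, and SLC24A5 and TYRP1 rose to 0.687 and 0.505 CPM (camera adjusted p = 0.0439, and adjusted p = 0.341 with an estimated correlation). Without T27 replicate 1 the T27 mean of DCT was 0.111 CPM, and TYRP1 had no count in the other T27 libraries. The pigment call was lost without T29 replicate 3 (adjusted p 0.0517) and without T30 replicate 3 (0.0524). Of 9 connective tissue matrix genes 7 fell and 1 rose, with the same counts adjusted over the list alone. The fibrillin gene FBN2 went from 497.7 ± 22.2 to 78.1 ± 8.67 CPM, and the type VI collagen genes COL6A1, COL6A2 and COL6A3 had log2 changes of −2.01, −2.72 and −3.64 (camera adjusted p = 0.0143, and adjusted p = 0.341 with an estimated correlation).

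The neural crest, an embryonic cell population named in the title of the series, was represented by 6 measured genes of 44 fixed, of which 5 fell and 1 rose, also 5 and 1 adjusted over the list alone. PRRX1 went from 100.7 ± 30.5 to 13.5 ± 1.42 CPM (SD, n = 3) and ALX1 from 7.31 ± 1.70 to 1.11 ± 0.265 CPM. RET and PAX7 had log2 changes of −0.67 and −1.27. The endothelin receptor gene EDNRB rose from 1.19 to 2.99 CPM. Camera did not call the list (adjusted p = 0.154, and adjusted p = 0.408 with an estimated correlation).

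In all, 11376 of 16526 genes (68.8%) changed between T27 and T30, 5747 higher and 5629 lower at T30, and the stages did not overlap in 11821 genes (71.5%), where chance gives 10%. Most lists that camera did not call held both directions, and the erythroid list held falls alone. Genes that rose and fell numbered 9 and 8 of 25 for mucus and secretory pathway, 2 and 14 of 53 for mitochondrial respiration, 2 and 12 of 71 for cytosolic ribosomal proteins, 4 and 14 of 24 for developmental signalling, and 2 and 5 of 8 for basement membrane. They numbered 5 and 6 of 15 for neurons, 6 and 2 of 13 for liver, 0 and 7 of 8 for erythroid cells, 3 and 3 of 6 for gill and ionocytes, 1 and 4 of 6 for stress and immediate early genes, 2 and 2 of 6 for cartilage, 1 and 3 of 5 for endothelium, and 1 and 4 of 5 for epithelium. The same counts held adjusted over the list alone, except for mitochondrial respiration (1 and 13) and ribosomal proteins (1 and 1). Median and mean differed in sign for cartilage (median log2 change 0.04, mean −0.35) and for gill and ionocytes (−0.11 and 0.19).

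**Figure D3:**
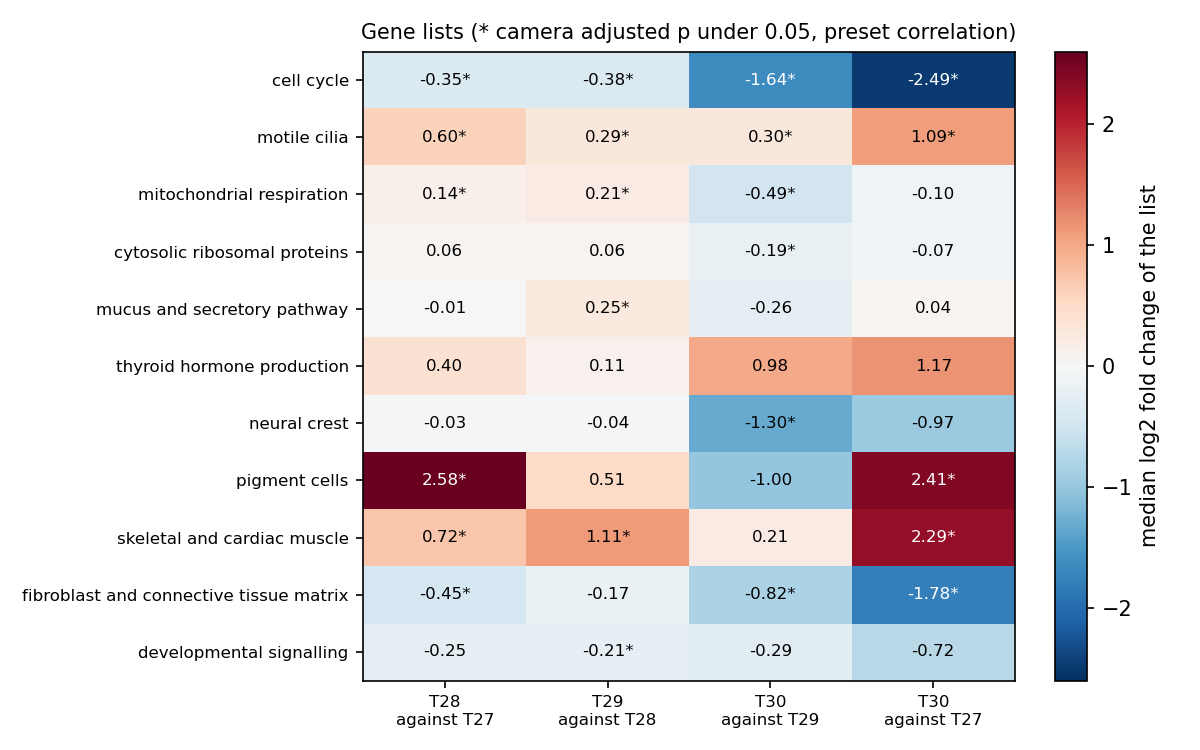
Median log2 fold change (colour and number) of 11 gene lists in the 4 contrasts; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The cell cycle list was negative and the motile cilia list positive in each contrast, and thyroid hormone production had its largest step from T29 to T30 (0.98), without a call.

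The comparison of T28 with T27 asked what changed at the first step. SLC5A5 rose 1.55-fold (log2 0.64, SE 0.13), from 5.93 ± 0.902 to 9.23 ± 0.611 CPM (SD, n = 3), and LRP2 rose 2.98-fold (log2 1.57, SE 0.17). PAX1 rose 2.16-fold and SOX2 1.49-fold, and ISL1 fell by 0.60 (SE 0.10) and CTSB by 0.39 (SE 0.10) on the log2 scale. Of the thyroid hormone production list 3 rose and 1 fell of 11 (3 and 1 adjusted over the list alone; camera adjusted p = 0.185, adjusted p = 0.493 with an estimated correlation, and 0.00343 with fry). Of the regulators 2 rose and 1 fell of 7 (2 and 2 adjusted over the list alone; adjusted p = 0.876). The CTSB call was lost without T27 replicate 3 (log2 change −0.32, edgeR adjusted p 0.0654).

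Pigment cell genes rose from low levels between T27 and T28, 7 of 8 measured, also 7 adjusted over the list alone, with a median log2 change of 2.58. DCT went from 0.225 ± 0.202 to 5.26 ± 0.487 CPM (SD, n = 3), PMEL from 0.975 to 6.20 CPM, TYRP1 from 0.0402 to 1.6 CPM and TYR, the tyrosinase of melanin synthesis, from 0.222 to 1.27 CPM. This camera call (adjusted p = 1.36e-06) also held with an estimated correlation (adjusted p = 0.0348 with an estimated correlation). Outside that list GPNMB rose from 0.245 to 4.65 CPM, the nucleoside transporter gene SLC28A3 from 0.401 to 2.99 CPM and C1QTNF3 from 0.314 to 2.43 CPM. Without T27 replicate 1 the T27 means of DCT, GPNMB and C1QTNF3 were 0.111, 0.127 and 0.0334 CPM, the last on 2 counts, and TYRP1 had no count at T27; the log2 change of C1QTNF3 was 2.89, and 4.35 with voom. The largest falls among named genes were in APOC3 (log2 −2.14, SE 0.24), GPR157 (−1.83, SE 0.20), SPATA1 (−1.57, SE 0.29) and CETP, a plasma lipid transfer protein (−1.49, SE 0.25). Of these, SPATA1 rose 3.15-fold over the whole span from T27 to T30.

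Motile cilia genes rose in 52 of 59 members and fell in none (54 and 0 adjusted over the list alone), for example SPEF2 1.84-fold, CFAP251 1.92-fold and DNAAF4 1.90-fold (camera adjusted p = 1.46e-20, and adjusted p = 0.382 with an estimated correlation). Cell cycle genes fell in 28 of 42 (38 adjusted over the list alone), among them the replication genes MCM3, MCM5, POLE and DNMT1 with log2 changes of −0.55, −0.57, −0.56 and −0.42 (adjusted p = 1.90e-13, and adjusted p = 0.195 with an estimated correlation). Muscle genes rose in 6 of 12 (7 adjusted over the list alone), with TNNC1 at 2.35-fold, MYOM1 at 3.89-fold, MYBPC1 at 2.90-fold and NEB at 2.76-fold (adjusted p = 0.00382, and adjusted p = 0.615 with an estimated correlation). Without T27 replicate 1 the MYOM1 rise was 6.51-fold. Connective tissue genes fell in 6 of 9, and 7 fell and 1 rose adjusted over the list alone, with FBN2, PDGFRA, MMP2 and SPARC at −0.83, −0.79, −0.70 and −0.45 (adjusted p = 0.0104, and adjusted p = 0.382 with an estimated correlation). Of 53 respiration genes 4 rose, namely NDUFB8, COX4I1, NDUFB4 and NDUFA7, each by 1.20-fold to 1.28-fold, and 0 adjusted over the list alone. That call (adjusted p = 0.00136) was lost with an estimated correlation (adjusted p = 0.661 with an estimated correlation), with fry (adjusted p = 0.132) and without T27 replicate 2 (adjusted p 0.0757). COX4I1, NDUFB4 and NDUFA7 each lost their edgeR call without at least 4 of the 12 libraries in turn, for example without T27 replicate 2 with adjusted p 0.107, 0.101 and 0.155.

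In all, 4301 of 16526 genes (26%) changed at this step, 2359 higher and 1942 lower at T28. The stages did not overlap in 7572 genes (45.8%), where chance gives 10%. Without T27 replicate 1, the T27 library nearest to T28, the count was 4079. It was 2926 without T27 replicate 2, 3119 without T27 replicate 3, and 3354, 3145 and 3176 without T28 replicates 1, 2 and 3.

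The comparison of T29 with T28 gave the fewest changed genes of the 3 steps, and SLC5A5 was the only thyroid hormone production gene that rose. It rose 1.64-fold (log2 0.72, SE 0.12), from 9.23 ± 0.611 to 15.2 ± 1.61 CPM (SD, n = 3). PAX2 fell by 0.53 (SE 0.08), LRP2 by 0.54 (SE 0.16) and CTSB by 0.40 (SE 0.11) on the log2 scale. Of the thyroid hormone production list 1 rose and 2 fell of 11 (3 and 2 adjusted over the list alone; camera adjusted p = 0.812), and of the regulators 0 rose and 1 fell of 7 (1 and 3 adjusted over the list alone; adjusted p = 0.433). The LRP2 call was lost without T28 replicate 1, T28 replicate 3, T29 replicate 1 or T29 replicate 3 (edgeR adjusted p 0.177, 0.0531, 0.103 and 0.121) and in the fit of only both stages (0.055). The CTSB call was lost without any of the 3 T28 libraries or T29 replicates 1 or 2 (0.0506 to 0.0913).

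The named genes with the largest rises at this step were AMPD1 at 4.88-fold, SLC7A11 at 4.68-fold, DNASE1L3 at 3.97-fold and the muscle chaperone HSPB7 at 3.75-fold. ACOD1 went from 19.4 ± 10.4 to 3.34 ± 1.76 CPM, the haem-binding HPX from 75.8 ± 1.93 to 26.8 ± 0.980 CPM, KLHL14 from 6.25 to 2.42 CPM and GPR157 from 3.57 to 1.64 CPM. The HPX fall followed a 3.92-fold rise from 19.3 CPM at T27. HPX was not called between T27 and T30 (log2 change 0.155, edgeR adjusted p 0.469). Muscle genes rose in 8 of 12 (10 adjusted over the list alone), with ACTN2 at 2.88-fold, TTN at 2.56-fold, TCAP at 2.43-fold and LDB3 at 2.40-fold (camera adjusted p = 1.24e-06, and adjusted p = 0.474 with an estimated correlation). Secretory pathway genes rose in 9 of 25 (15 adjusted over the list alone), among them PDIA4, SRPRB, DNAJB9 and MANF of the endoplasmic reticulum, by 1.25-fold to 1.44-fold (adjusted p = 8.93e-07, and adjusted p = 0.474 with an estimated correlation). The DNAJB9 call was lost without T28 replicate 2 (edgeR adjusted p 0.0575), and the MANF call without T28 replicate 1 or T29 replicate 1 (0.0517 and 0.0519).

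Cell cycle genes fell again between T28 and T29 in 30 of 42 members (38 adjusted over the list alone), with RRM1, MCM7, SMC4 and MCM4 at −0.74, −0.59, −0.44 and −0.54 (camera adjusted p = 1.08e-19, and adjusted p = 0.143 with an estimated correlation). Motile cilia genes rose in 20 of 59 and fell in 1 (29 and 1 adjusted over the list alone), with CFAP69, RSPH9, CFAP47 and ENKUR at 1.41-fold to 1.57-fold (adjusted p = 1.64e-08, adjusted p = 0.602 with an estimated correlation, and adjusted p = 0.0911 with fry). Respiration genes rose in 7 of 53 (15 adjusted over the list alone), with NDUFS8 at 1.49-fold, and SDHC and UQCRFS1 at 1.21-fold each (adjusted p = 4.91e-09, adjusted p = 0.602 with an estimated correlation, and adjusted p = 0.0885 with fry). The SDHC and UQCRFS1 calls were lost without any of several single libraries, T28 replicate 1 among them (edgeR adjusted p 0.0904 and 0.0681). Of 24 developmental signalling genes 3 fell and 1 rose (4 and 1 adjusted over the list alone). The Notch ligand gene JAG1 fell by 0.59, the receptor gene FGFR2 by 0.51 and the secreted inhibitor FST by 0.45 on the log2 scale, and HES1 had −0.57 without a call (edgeR adjusted p 0.0538). That list's call (adjusted p = 0.0104, and adjusted p = 0.229 with an estimated correlation) was lost without T29 replicate 2 (adjusted p 0.063). The FGFR2 and FST calls were each lost without T28 replicate 1 (edgeR adjusted p 0.0751 and 0.0951) and without other single libraries.

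In all, 2215 of 16526 genes (13.4%) changed between T28 and T29, 1299 higher and 916 lower at T29, and the stages did not overlap in 5619 genes (34%), where chance gives 10%. The count was 1192 without T28 replicate 1, 1346 without T28 replicate 2, 1451 without T28 replicate 3 and 1259 without T29 replicate 1.

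The comparison of T30 with T29 gave the most changed genes of the 3 steps. SLC5A5 rose 6.97-fold (log2 2.80, SE 0.12) from 15.2 ± 1.61 to 105.6 ± 12.2 CPM (SD, n = 3), LRP2 4.31-fold (log2 2.11, SE 0.16) and IYD 2.28-fold (log2 1.19, SE 0.10). SLC5A8 rose 2.48-fold and ANO1 1.39-fold. PAX2 rose 2.72-fold (log2 1.44, SE 0.08), HHEX 1.67-fold and FOXA2 1.22-fold. CTSB fell by 1.43 (SE 0.11), PAX9 by 1.21 (SE 0.16), PAX1 by 0.90 (SE 0.14), KCNQ1 by 0.64 (SE 0.23) and ISL1 by 0.53 (SE 0.10) on the log2 scale.

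Of 11 thyroid hormone production genes 6 rose and 2 fell at this step, the same adjusted over the list alone, with a median log2 change of 0.98. The list was not called (camera adjusted p = 0.0566, and adjusted p = 0.507 with an estimated correlation). With the preset correlation it passed without T27 replicate 1, T29 replicate 2 or T30 replicate 3 (adjusted p 0.0488, 0.0419 and 0.0381) and after thinning (0.0421), and fry gave adjusted p = 5.45e-06. Of 7 regulators 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.998; median log2 change −0.13, mean −0.04, with camera's direction up). The ANO1 call was lost without T29 replicate 3 (edgeR adjusted p 0.194), T30 replicates 1 or 2 (0.19 and 0.119), T27 replicates 1 or 2 (0.0502 and 0.0524) or T28 replicate 1 (0.0578), and in the fit of only both stages (0.0533). The KCNQ1 call was lost without T29 replicates 2 or 3 or T30 replicates 1 or 2 (0.0504 to 0.12), in the fit of only both stages (0.0645), after thinning (0.0543) and with voom (0.0559).

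SLC7A11 had the largest rise of the named genes, from 8.85 ± 3.04 to 259.5 ± 57.0 CPM (SD, n = 3), 29.2-fold. GLDC, the decarboxylase of glycine cleavage, rose 17.8-fold from 4.47 ± 0.283 to 79.3 ± 14 CPM and the myosin gene MYO3A 15.8-fold from 43.5 ± 2.16 to 687.2 ± 194.7 CPM. CTHRC1 went from 16.6 ± 4.23 to 1.6 ± 0.129 CPM and TH from 3.70 ± 0.468 to 0.389 ± 0.108 CPM. All 42 cell cycle genes fell (42 adjusted over the list alone; median log2 change −1.64), with PLK1, UBE2C, KIF11 and CENPE at −2.93, −2.90, −2.53 and −1.96 and SEs of 0.07 to 0.10 (camera adjusted p = 1.04e-22, and adjusted p = 0.0968 with an estimated correlation).

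Most respiration genes fell between T29 and T30, and so did a part of the ribosomal protein genes. Of 53 respiration genes 48 fell and none rose (50 and 0 adjusted over the list alone; median log2 change −0.49), with ATP5F1C, NDUFS6, SDHD and ATP5PB at −0.69, −0.66, −0.60 and −0.65 (camera adjusted p = 3.21e-09, and adjusted p = 0.507 with an estimated correlation). Of 71 ribosomal protein genes 24 fell and none rose (17 and 0 adjusted over the list alone; median −0.19), with RPS25, RPL35A, RPLP0 and RPL24 at −0.75, −0.56, −0.52 and −0.43 (adjusted p = 0.00699, and adjusted p = 0.794 with an estimated correlation). The ribosomal call was lost without T29 replicate 3 (adjusted p 0.0674) or T30 replicate 1 (0.16) and with fry (adjusted p = 0.13). Motile cilia genes rose in 31 of 59 and fell in 7 (32 and 7 adjusted over the list alone), with DNAH5 at 3.28-fold, CFAP100 at 2.91-fold, CFAP221 at 2.29-fold and CFAP65 at 1.85-fold (adjusted p = 0.0014, and adjusted p = 0.67 with an estimated correlation).

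All 6 measured neural crest genes fell between T29 and T30, also 6 adjusted over the list alone (median log2 change −1.30). ALX1 went from 4.25 ± 0.504 to 1.11 ± 0.265 CPM (SD, n = 3), PRRX1 from 35.1 ± 11.4 to 13.5 ± 1.42 CPM and EDNRB from 7.51 ± 0.503 to 2.99 ± 0.346 CPM (camera adjusted p = 0.00722, and adjusted p = 0.413 with an estimated correlation). Of 9 connective tissue genes 6 fell and 1 rose, the same adjusted over the list alone, with COL6A3, COL6A2, COL6A1 and FBN2 at −2.71, −2.17, −1.67 and −1.30. That call (adjusted p = 0.0478, and adjusted p = 0.507 with an estimated correlation) was lost without T29 replicate 3, T30 replicate 1 or T30 replicate 2 (adjusted p 0.0605, 0.0711 and 0.0527).

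Of 8 pigment cell genes 5 fell between T29 and T30 and none rose (the same adjusted over the list alone; median log2 change −1.001). PMEL went from 10.1 ± 1.06 to 3.89 ± 0.325 CPM (SD, n = 3) and TYRP1 from 2.10 to 0.505 CPM. Camera did not call the list at this step (adjusted p = 0.18, and adjusted p = 0.507 with an estimated correlation), while fry gave adjusted p = 0.000891. Muscle genes rose in 5 of 12 and fell in 1, secretory pathway genes rose in 6 of 25 and fell in 11 (6 and 12 adjusted over the list alone), and developmental signalling genes rose in 5 of 24 and fell in 12. Camera called none of these lists at this step (adjusted p = 0.419, 0.18 and 0.18), and fry gave adjusted p 0.195, 0.00811 and 4.59e-05.

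In all, 9973 of 16526 genes (60.3%) changed between T29 and T30, 5006 higher and 4967 lower at T30, and the stages did not overlap in 10480 genes (63.4%), where chance gives 10%. The change of this step differed from that of the T27 to T28 step in 7398 genes.

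**Figure D4:**
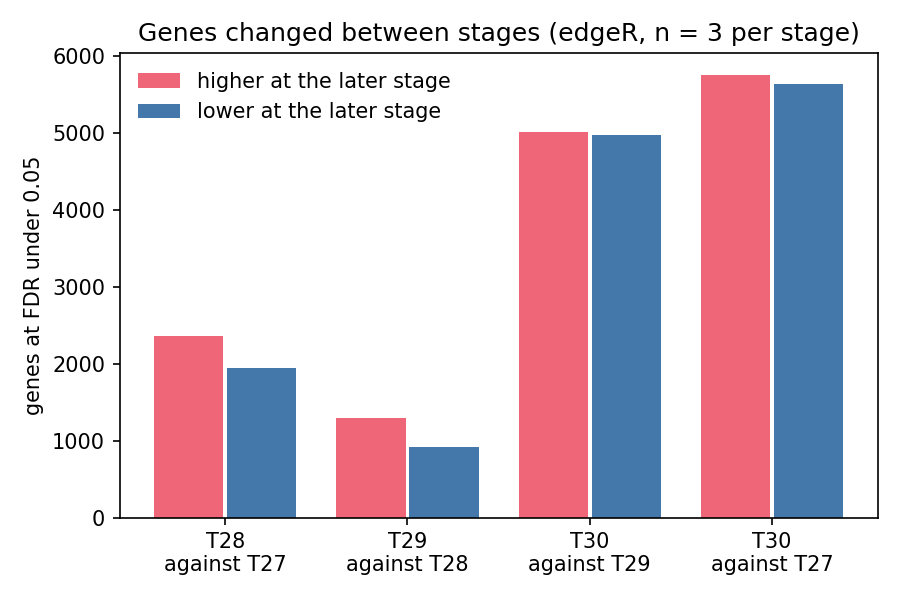
Genes past an adjusted p of 0.05 (edgeR) in each contrast, as bars from 0 for genes higher and genes lower at the later stage (n = 3 per stage). The T29 to T30 step had 5006 higher and 4967 lower genes, against 2359 and 1942 for T27 to T28 and 1299 and 916 for T28 to T29.

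The authors' deposited table of z-scores set the lamprey stages beside Ciona and zebrafish, the former a tunicate with an endostyle and the latter a fish with a thyroid. Of its 1671 genes 946 (56.6%) had their highest score in Ciona, 310 at T30, 220 at T27, 93 at T29, 57 at T28 and 45 in zebrafish. The lowest score was at T30 for 662 genes and at T27 for 515. In the authors' deposited table DUOX1, an oxidase that makes hydrogen peroxide, scored 0.99 in Ciona, −1.13 at T27, 1.41 at T30 and −0.07 in zebrafish, and its maturation factor DUOXA2 scored 0.77, −1.18, 1.49 and 0.13 in the same columns. No row of the count table carries either of these symbols, so they have no value from the counts.

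For 12 of 21 motile cilia genes in the authors' deposited table the highest score was at T30, and all 21 scored higher at T30 than at T27. All 18 cell cycle genes scored lower at T30 than at T27 there, with a median score of −1.9 at T30. Of 42 ribosomal protein genes 41, and of 15 respiration genes 12, scored highest in Ciona in the authors' deposited table. So did 56.6% of all its 1671 genes, and the unit that was standardised is not given. A score is relative to its own gene's mean over the 6 columns, so it ranks columns within a gene and gives no level, error or test between species. Among 1238 genes of the authors' deposited table called here between T27 and T30, the sign of the difference of the scores was that of the fitted change in 1194 (96.4%), and the Spearman correlation across 1654 genes was 0.885, where genes are not independent replicates. The lamprey columns carry the names of the same stages, and which libraries they were made from is not given in the sources used here.

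**Figure D5:**
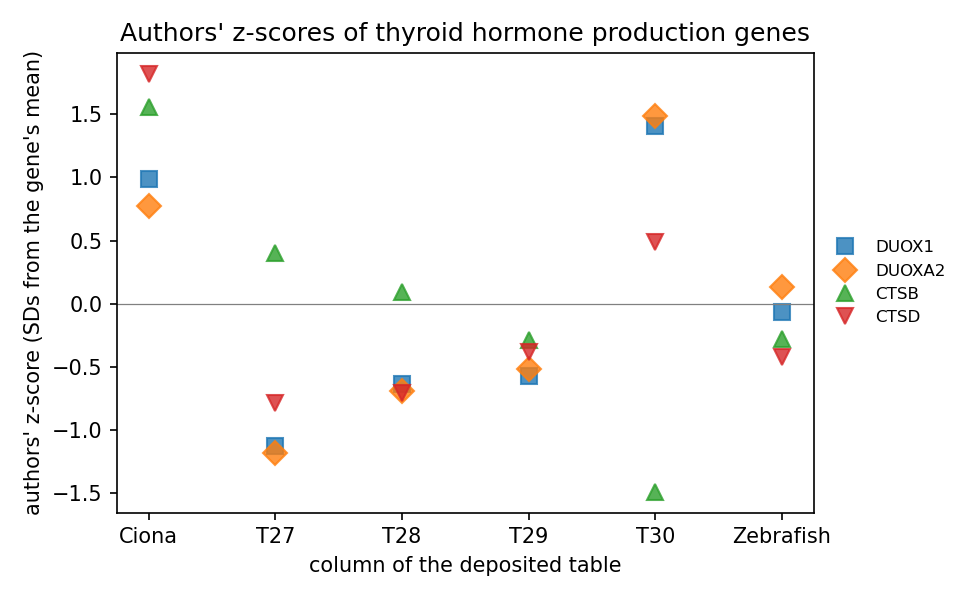
The authors' z-scores (SDs from each gene's mean over 6 columns) of 4 thyroid hormone production genes in their table, by column; each point is the authors' value with no replicate. DUOX1 and DUOXA2 have their highest scores at T30 (1.41 and 1.49), CTSB and CTSD in Ciona (1.56 and 1.82).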

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

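Tests of depth, abundant genes and scaling had their outcomes written down before they were run, and the thinned libraries and the fit without abundant genes were added after seeing the data. The splits were described after the counts were known. The T29 to T30 step and the T27 to T28 step share no library, and their difference was tested for every list in the same model. It passed for 5 lists. The values are medians over the members of each gene's own difference between the steps, on the log2 scale. Cell cycle genes differed by −1.20 (adjusted p = 2.48e-19 with camera, adjusted p = 0.075 with an estimated correlation). Pigment cell genes differed by −4.05 (0.000345, and adjusted p = 0.075 with an estimated correlation), with 6 of 8 members called and none the other way. Neural crest genes differed by −1.29 (0.0169, and adjusted p = 0.378 with an estimated correlation), mitochondrial respiration by −0.66 (1.54e-11, and adjusted p = 0.555 with an estimated correlation) and ribosomal proteins by −0.26 (0.00208, and adjusted p = 0.76 with an estimated correlation).

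The T29 to T30 step changed 9973 genes, against 4301 and 2215 for the earlier steps. A difference in depth does not account for this, since 9853 genes changed after thinning, against 4218 for T28 against T27. A few abundant genes do not either, with 9911 against 4274 without the 100 most abundant. Over both other scalings the lowest count was 9952, against at most 4375 for the first step. The scalings gave close medians over all genes between T29 and T30 (log2 0.018 to 0.064), so they cannot test a shift shared by most genes. A longer developmental time between T29 and T30 than between the other stages, batch, and a real change of pace stay open, since the sources used here give neither the ages nor the batches, and no biological explanation was tested.

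For the change over any stage, 1 of 100 splits of the libraries, the real split, gave as many genes (12697, highest other 8041). That share is under 0.05, but the other splits put libraries of different stages in one group. Differences between animals, pools or batches are not excluded by it, since the replicates may be technical. With 3 libraries against 3 there are 10 splits, and no share under 0.05 can be reached. For T28 against T27 the real split alone, 1 of 10, gave 4301 genes, with 0 as the highest other. The same was seen for T29 against T28 (1 split, 2215, highest other 0), T30 against T29 (1 split, 9973, highest other 0) and T30 against T27 (1 split, 11376, highest other 0), all with edgeR.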

How the results depend on the processing

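Thinning and the fit without abundant genes were added after seeing the data. Counts past the threshold stayed within 1.5 times the main count under both scalings, both filters, DESeq2, voom, thinning, the fit without the 100 most abundant genes and the fit of only 2 stages. Smaller counts followed from stricter thresholds. At 0.01, T28 against T27 had 2396 genes and T29 against T28 852. With a log2 fold of at least 1 the counts were 1108, 518, 3289 (T30 against T29) and 5110 (T30 against T27), and the share higher went from 54.8, 58.6, 50.2 and 50.5% to 77, 75.1, 60.5 and 60.9%. Leaving out each library gave 2926 to 4533 genes for T28 against T27, 1192 (without T28 replicate 1) to 2395 for T29 against T28, 9011 to 10027 for T30 against T29, 10741 to 11636 for T30 against T27, and 11897 to 12640 for any stage. Lists called numbered 6, 6, 6 and 5. With an estimated correlation they numbered 1, 0, 0 and 0, and with fry, which does not compare a list with other genes, 10 for T28 against T27, 4 for T29 against T28, 16 for T30 against T29 and 14 for T30 against T27. Leaving out a library gave 5 to 7, 6 to 7, 4 to 7 and 4 to 8 lists, the 8 without T27 replicate 2. The thyroid hormone production median for T29 against T28, not called, was −0.025 without T29 replicate 2 and 0.137 without T29 replicate 1, the range over the libraries. Of 176 values of the 119 genes that the naming rule selected, 159 stayed on their side of the threshold under all alternatives of scaling, filter, test, replicate block, samples, thinning and abundant genes, and none changed sign. Of the 175 called, 17 did not pass at 0.01 and 66 had a log2 fold under 1. HES1, not called, passed under 6 alternatives. The 16 lost calls each had at least 1 loss when a library was left out. Beyond the sample numbers, the cause was not tested.

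The replicate number did not pair the samples across all stages. Deviations of same-numbered libraries correlated by −0.289 to 0.241, 4 of 18 pairs lay over 0.1 and 6 of 12 libraries correlated best with their own number. The pairs over 0.1 were of T27, T29 and T30 (replicate 3 with 0.241, 0.191 and 0.106, replicate 1 with 0.139). Replicate 3 of T28 and T29 gave −0.289, and replicate 2 of T27 and T30 −0.059. The median was 0.003 for same-numbered pairs and 0.005 for other pairs, and T28 replicate 3 with T29 replicate 1 gave 0.239. The stages T27, T29 and T30 were singled out from these same correlations, which therefore do not show pairing. Pairing by number among them stays open. With the replicate block 4063, 2007, 9821 and 11276 genes were called, and no call of these genes was lost.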

Other observations

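Genes of serine, glycine and one-carbon metabolism were examined after GLDC had been seen among the largest rises, in a list without GLDC and PHGDH. Of 22 measured members 13 rose and 6 fell between T29 and T30, with a median log2 change of 0.377. The members named here are examples that the naming rule does not cover, and most of them rose by more than that median. CTH, which makes cysteine from cystathionine, went from 91.7 ± 11.1 to 495.3 ± 44.4 CPM (SD, n = 3), AHCY from 471.9 ± 22.0 to 1887 ± 171.4 CPM, ALDH1L2 from 7.50 ± 0.127 to 70.7 ± 4.39 CPM, GNMT from 14.5 to 111.9 CPM and the serine synthesis genes PSPH and PSAT1 5.30-fold and 4.14-fold. SHMT2, the mitochondrial serine hydroxymethyltransferase, rose 2.75-fold. SHMT1, its cytosolic form, and TYMS fell, to 0.382-fold and 0.251-fold.

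The lists of this part were chosen after the gene tables had been seen, and their expected directions were written before the tests were run. Their p-values come from the libraries that led to the lists, so they describe these data and are not independent tests. The serine, glycine and one-carbon list rose between T29 and T30 (median log2 change 0.377, camera adjusted p = 0.0444 over 7 lists, adjusted p = 0.296 with an estimated correlation). Transport and basal body genes of the cilium rose between T27 and T30 (median 0.49, adjusted p = 0.000201, adjusted p = 0.317 with an estimated correlation), with 32 of 48 higher and 5 lower. DNA repair genes fell between T29 and T30 (median −0.304, adjusted p = 0.00737, adjusted p = 0.53 with an estimated correlation), with 26 of 48 lower and 6 higher, as did proteasome genes, 33 of 35 lower and none higher (median −0.778, adjusted p = 4.30e-12, adjusted p = 0.296 with an estimated correlation), and spliceosome genes, 40 of 54 lower and 5 higher (median −0.439, adjusted p = 1.84e-07, adjusted p = 0.296 with an estimated correlation). A rise of genes that handle hydrogen peroxide at T30 was not seen (median −0.015, adjusted p = 0.728, 7 higher and 10 lower of 23). Lysosome genes were not called between T27 and T30 (median 0.191, adjusted p = 0.374), with 19 higher and 10 lower of 39.

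The T27 to T28 and T29 to T30 steps, which share no library, were compared to ask whether changes of the former were undone in the latter. A change undone between T28 and T29 lies outside this comparison. Across genes the changes correlated positively (Pearson 0.2, Spearman 0.216 over 16526 genes, which are not independent replicates). Genes that moved the same way in both numbered 2186, where independent lists give 1298.3, and genes that moved opposite ways numbered 788, where independent lists give 1297.3. A general reversal over these steps is thus not seen. The pigment list had median log2 changes of 2.578 and then −1.001, the latter without a camera call, and respiration 0.138 and −0.494. Neural crest genes had no shared change at the first step to undo (median −0.027, 2 rose and 2 fell). Camera with the preset correlation called the step difference for these lists (adjusted p = 0.075, 0.378 and 0.555 with an estimated correlation for pigment, neural crest and respiration). Such a difference alone is no reversal, since the cell cycle list also differed and fell at both steps.

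SLC5A5 and IYD rose between T29 and T30, and the tests here were described after these values were seen. The choice among the scalings used does not account for it, since the lowest fold of both genes over both other scalings was 2.29. Nor does a single library, with a lowest fold of 2.13 over the 12 fits that leave a library out. The median log2 change over all genes was 0.018 with TMM, 0.02 with size factors and 0.064 with upper quartile scaling. With scalings so close, a shift shared by most genes was not tested. A larger share of cells that express both genes may contribute. Such a share alone would raise them by a common factor, and the SLC5A5 change exceeded the IYD change by 1.61 (SE 0.159) on the log2 scale. Because other cells may express IYD, this does not exclude it, and more cells and more transcript per cell cannot be told apart.

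Muscle genes rose between T27 and T30 while connective tissue genes fell, and both tests here were described after the values were seen. The connective tissue median was −1.782 (log2) and the muscle median 2.29, so markers of other tissue did not all rise together. This argues only against a lower share of endostyle that raises all other tissue alike. A lower share of endostyle with more muscle in its place stays open. Between T29 and T30, 9 of 12 muscle genes departed from the mean of their list, TCAP by 1.91 and UNC45B by −1.23, so a larger share of muscle of constant makeup may be only part of the change, and expression in other tissue keeps it open.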
